A study of Arabidopsis thaliana with 6 samples.

How the data were processed

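The labels name the samples as 35S:GR-TCP5 seedlings, 12 days old, and give no organ. Most listed root transcripts were nearly absent from the 4 first-run libraries, so whether whole seedlings were used for them is not known. Plants were grown at 22 °C under 14 h of light and 10 h of dark. Per the labels' protocols, the DEX solution held 10 mM dexamethasone, 0.1% ethanol and 0.015% of the wetting agent silwet, and the mock solution lacked dexamethasone. The dose is given as labelled; it is far above the micromolar doses usual for this treatment, so its unit is in doubt. Libraries were made with a TruSeq RNA v2 kit, which does not mark strand, per the labels' protocols.

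Each deposited file held raw read counts per gene for 1 library, in exons, in introns and as their sum, per the file headers. STAR and DESeq2 are named in the submitters' processing notes, without versions. The counter, genome build and annotation are not given in the sources used here. Between 16.6% and 25.8% of the exon counts from 1 to 20 were odd numbers. An excess of even counts would arise if both mates of a pair were counted, which was not tested. In that case the counts would overstate the number of independent fragments. Without strand, reads of overlapping or antisense genes cannot be told apart. Of the 1024 changed genes 271 overlapped another listed locus, and for 50 of these an overlapping locus changed in the same direction. The files also gave a gene length, in bases, as deposited by the authors under another unit than counts.

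The files listed 38194 loci. Names, overlaps and upstream sequence came from the TAIR10.1 RefSeq annotation, which matched 37898 loci. The exonic length equalled that in the files for 78.7% of the loci with exons in it. No coordinates are given, because the build behind the files is not known.

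Exon counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood fit and F-test), with Benjamini-Hochberg adjustment at 0.05. All 6 libraries entered, with sequencing run and treatment as terms. The design, the alternatives, the rule for named genes and the 31 gene lists were fixed before the data were examined. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and fry as alternatives. Alternatives included DESeq2 1.42.0, limma-voom, other scalings and filters, no run term, a replicate block, the first run alone and each library left out.

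Genes were named by a fixed rule. It took TCP5, each KNOX or BEL-like gene that passed, and KNAT3 and BLH2 whatever they showed, from knowledge of the study. It took the 12 largest rises and 12 largest falls among changed genes with a mean of at least 1 CPM and the same direction in both runs, the 5 rises and 5 falls with the smallest adjusted p, and up to 4 changed members of each list. Genes named outside it are said to have been named or chosen after their values were seen. Fold changes are DEX over mock. Scalings other than TMM turned the sign of no named gene, and the median log2 fold change of all genes stayed between 0.00 and 0.05.

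Depth ranged from 33428836 to 76859163 exon counts per library, and introns held 2.07% to 2.57% of counts. A pair of loci beside annotated ribosomal RNA genes took 4.57% of counts in DEX replicate 1, 1.58% and 2.25% in mock replicates 1 and 2, and at most 0.127% in the others. Libraries of the same number deviated together from their group means (r over genes 0.63, 0.61 and 0.88 for replicates 1, 2 and 3). Since each r exceeded 0.1, the rule set for pairing was met and the replicate block is reported, but the data show only a pairing by run. DEX replicate 1 correlated more with mock replicate 2 (0.688) and DEX replicate 2 with mock replicate 1 (0.686) than with their own numbers, and within the first run the difference between DEX replicates 1 and 2 did not follow that between mock replicates 1 and 2 (r = −0.14 over genes). No library duplicated another. The lowest chi-square per degree of freedom between 2 libraries was 28.7.

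The test was checked on simulated data for DEX against mock, with 21934 genes, 200 of them changed. With each gene's own dispersion it recovered 32.8%, 59.7% and 89.4% of changes of 1.5-, 2- and 4-fold, and 16.0% of its calls were false, at genes with dispersions far above the trend. With trend dispersions it recovered 32.8%, 70.1% and 93.9%, and 3.68% of calls were false. Camera with the preset correlation called 3 of 3 shifted lists and 2 of 26 lists with no shifted member. The genes were simulated independently of each other, so this does not measure false calls of lists whose members are correlated.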

Results

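The transcriptome of Arabidopsis thaliana seedlings carrying 35S:GR-TCP5 was measured by RNA sequencing after treatment with dexamethasone (DEX) or a mock solution. TCP5 is a CIN-class TCP transcription factor. In this line it is joined to the hormone-binding part of the glucocorticoid receptor (GR) and driven by the constitutive 35S promoter, so that DEX lets the protein enter the nucleus. Seedlings were 12 days old and were treated for 4 h. No plants without the construct were included, so effects of dexamethasone itself cannot be told from those of TCP5. Each group held 3 libraries, and the libraries totalled 33428836 to 76859163 exon counts. Replicates 1 and 2 of both groups came from one sequencing run and replicate 3 of both groups from another. The first-run libraries held 58720568 and 61179355 counts with DEX and 71223420 and 76859163 with mock. The second-run libraries held 35098276 with DEX and 33428836 with mock. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these libraries. Levels are CPM, counts scaled to a common library size after TMM normalisation, except those of the listed root genes, which are CPM on the raw library totals. Errors on log2 fold changes are standard errors (SE).

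The first comparison asked whether the TCP5 transcript itself differed between the groups, since the transgene should be present in every library. TCP5 (AT5G60970) was at 487 ± 414 CPM with DEX and 599 ± 501 CPM with mock (SD, n = 3), and the 6 libraries ranged from 233 to 1177 CPM. Its log2 fold change was −0.31 ± 0.10 (SE), lower with DEX in 3 of 3 pairs, and did not pass the test (edgeR quasi-likelihood adjusted p = 0.152). The counts do not separate the transgene's transcripts from those of the native gene. The wide SD followed the sequencing run. TCP5 was at 964 and 1177 CPM in the second run, 3.85-fold above the first run.

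The series title names the KNOX and BEL-like homeodomain families, so the second comparison asked which of their members changed after DEX. BLH2 (AT4G36870), a BEL-like gene that limits leaf margin serration, rose from 27.3 ± 3.80 to 39.9 ± 3.54 CPM (SD, n = 3). Its log2 fold change was 0.55 ± 0.11 (adjusted p = 0.0333). KNAT1 (AT4G08150), a KNOX gene of the shoot meristem and stem, fell from 12.8 ± 2.75 to 7.55 ± 1.101 CPM, a log2 fold change of −0.75 ± 0.14 (adjusted p = 0.0231). KNAT3 (AT5G25220) was at 27.0 ± 0.97 CPM with mock and 33.7 ± 1.79 CPM with DEX. Its log2 fold change of 0.32 ± 0.09, higher with DEX in 3 of 3 pairs, did not pass over all genes (adjusted p = 0.0812).

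Of 20 KNOX and BEL-like genes tested, these 2 passed over all genes and 18 did not. Adjusted over the list alone, 1 KNOX gene rose (KNAT3) and 1 fell (KNAT1), and 2 BEL-like genes rose (BLH2 and BLH4) and 1 fell (BLH8). BLH4 had a log2 fold change of 0.34 ± 0.10 and BLH8 of −0.75 ± 0.19. Those 2 genes were named after their values were seen. The families were the authors' choice in a title written with these libraries in hand, so the counts adjusted over the list alone are not independent evidence. Neither family moved one way. The median log2 fold change was −0.14 for the KNOX genes (camera adjusted p = 0.851) and −0.15 for the BEL-like genes (camera adjusted p = 0.929). For the BEL-like genes the camera test pointed up, against the sign of the median, and it pointed down in the first run alone and without DEX replicate 1, DEX replicate 3 or mock replicate 3. With the replicate number as a block the adjusted p was 0.0685 for BLH2 and 0.148 for KNAT3, and 1 member of the families passed. DESeq2 called 5 members, KNAT3 among them, and without mock replicate 1 or 2 edgeR called 0 of them.

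**Figure D1:**
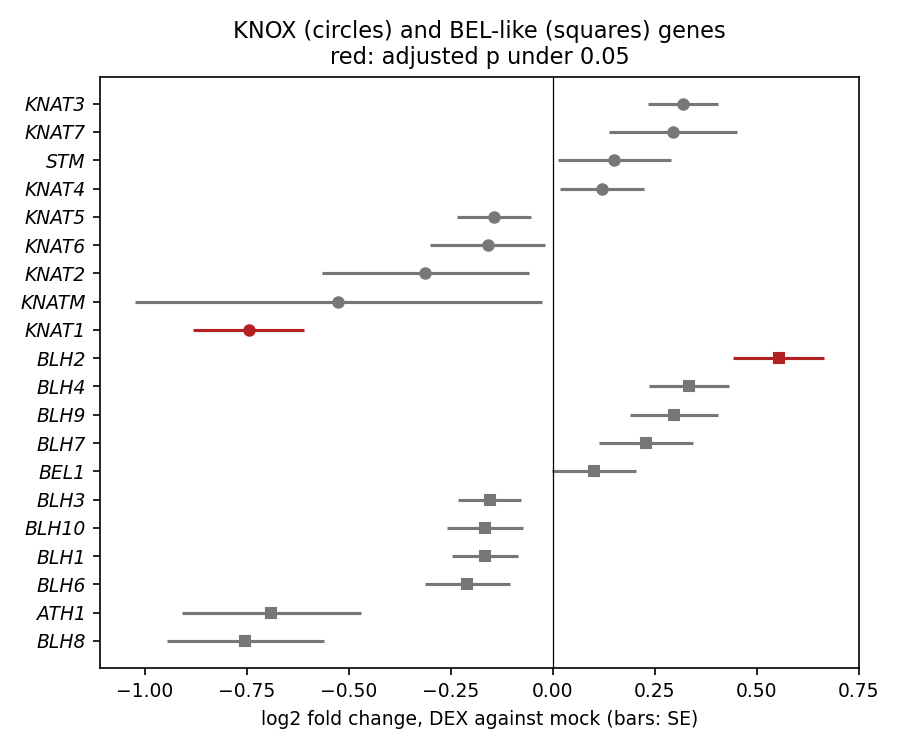
Log2 fold change of each tested KNOX gene (circles) and BEL-like gene (squares), DEX against mock, with bars for the SE. Red marks the 2 genes with an adjusted p under 0.05, KNAT1 at −0.75 and BLH2 at 0.55.

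The third comparison asked which genes changed across the transcriptome. Of 21934 genes tested, 238 rose and 786 fell after DEX, 1024 in all (edgeR quasi-likelihood test, adjusted p under 0.05). Changes of at least 2-fold made up 327 of these, with 44 rises and 283 falls. YUC5 (AT5G43890), a flavin monooxygenase of auxin synthesis, rose 8.84-fold. It was between 0.50 and 3.16 CPM in the mock libraries and between 5.47 and 24.7 CPM in the DEX libraries, with a log2 fold change of 3.14 ± 0.16 (adjusted p = 0.000435). Among changed genes with a mean of at least 1 CPM, the log2 fold change was larger only for AT1G52800, annotated as an oxygenase dependent on 2-oxoglutarate and iron, at 4.01 ± 0.79 (adjusted p = 0.0432). That gene was at 0.68 and 0.45 CPM in the first-run DEX libraries and 8.94 CPM in the second-run one. In the first run alone it had a log2 fold change of 2.79 (adjusted p = 0.116), below the 3.26 of YUC5, so its rank rests on the second-run pair. AT1G78820, annotated as a lectin, rose from 19.2 ± 2.72 to 85.8 ± 10.7 CPM (log2 fold change 2.15 ± 0.10).

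Among the 12 largest rises were also 2 genes of the UMAMIT transporter family, UMAMIT45 at a log2 fold change of 1.74 ± 0.13 and UMAMIT44 at 1.73 ± 0.16. The chitinase-domain gene ChiC rose by 1.93 ± 0.20 and the copper amine oxidase gene AT1G31690 by 2.40 ± 0.21. The uncharacterised AT4G01490 rose by 2.66 ± 0.38, AT2G34010 by 2.13 ± 0.27, AT3G25880 by 2.01 ± 0.32 and the tautomerase-family gene AT3G51660 by 1.54 ± 0.22. The glycosyltransferase gene AT1G01390 rose by 2.04 ± 0.21 and overlaps AT1G01380, with which it can share reads. ELI3-1, annotated as a cinnamyl alcohol dehydrogenase, and AT1G21670 had small adjusted p-values (both 0.0020) and log2 fold changes of 1.06 ± 0.09 and 1.01 ± 0.08.

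The largest fall among such genes was that of THAS1 (AT5G48010), the enzyme that makes the triterpene thalianol, at a log2 fold change of −4.23 ± 0.52 (adjusted p = 0.00628). Its neighbours in the thalianol gene cluster, CYP705A5 (−3.53 ± 0.26) and CYP708A2 (−2.78 ± 0.31), fell too. These 3 genes were nearly absent from the first run. THAS1 was at 14.2 CPM in the second-run mock library and 0.83 CPM in the DEX library of that run, and at most 0.22 CPM in each first-run library. Root transcripts had the same distribution over the runs and were lower in the second-run DEX library, as described below. The same held for CYP71A19, AT4G12170, AT3G45080 and AT4G28410, which were at most 0.60 CPM in each first-run library. Their levels in the second run, mock and then DEX, were 13.7 and 1.66 CPM, 13.6 and 1.21 CPM, 8.67 and 1.125 CPM, and 6.64 and 1.42 CPM. The levels of these 7 genes thus rest mainly on 1 library per group, where root transcripts differed too. Their first-run log2 fold changes, from those low levels, lay between −3.70 and −2.11. They were about as large as in the second run, or larger, for CYP71A19 (−3.70 and −3.02), AT3G45080 (−2.81 and −2.91) and AT4G28410 (−2.15 and −2.20). For THAS1, CYP705A5, CYP708A2 and AT4G12170 the computed fall was larger in the second run. However, these per-run values used a prior count of 2, which shrinks changes between levels near the floor. THAS1 and AT4G12170 were at 0 CPM in both first-run DEX libraries. Whether the falls of these genes differed between runs can therefore not be told. CYP71A19, which overlaps AT4G13300, fell by 3.61 on the log2 scale and AT4G12170, which overlaps AT4G05975, fell by 3.69. AT3G45080, the dirigent-family gene AT4G11190, AT5G37940 and AT3G09450 had log2 fold changes between −3.42 and −3.13. Those of AT5G37940 (−2.40 in the first run, −3.78 in the second) and AT4G11190 (−2.53 and −3.87) also owed much to the second-run pair. The oleosin gene OLEO4 fell by 2.999, UMAMIT22 by 2.90 and AT4G28410 by 2.56.

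Among the falls with the smallest adjusted p, the sterol desaturase gene CYP710A2 went from 37.2 ± 2.62 to 12.7 ± 1.99 CPM (log2 fold change −1.56 ± 0.10, adjusted p = 0.00112). The glucosinolate transporter gene GTR2 fell from 64.0 ± 14.3 to 28.3 ± 9.23 CPM (−1.202 ± 0.09) and overlaps AT5G62670. AT2G15020 fell by 1.86, AT1G27030 by 1.73 and AT3G11930 by 1.44 on the log2 scale.

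The 1024 calls depended on the run term. Without it edgeR called 0 genes (798 at an unadjusted p under 0.05), voom 0 and DESeq2 163. With the replicate number as a block edgeR called 571 genes, 546 of them shared with the 1024. The count was 304 without DEX replicate 2 and 279 without mock replicate 2. It was 613 without DEX replicate 3, 476 without mock replicate 1 and 630 without mock replicate 3. In data simulated with each gene's own dispersion and 200 changed genes, 23 of 144 calls (15.97%) were false. That share depends on how many genes truly change, so it does not carry over to the 1024 calls.

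**Figure D2:**
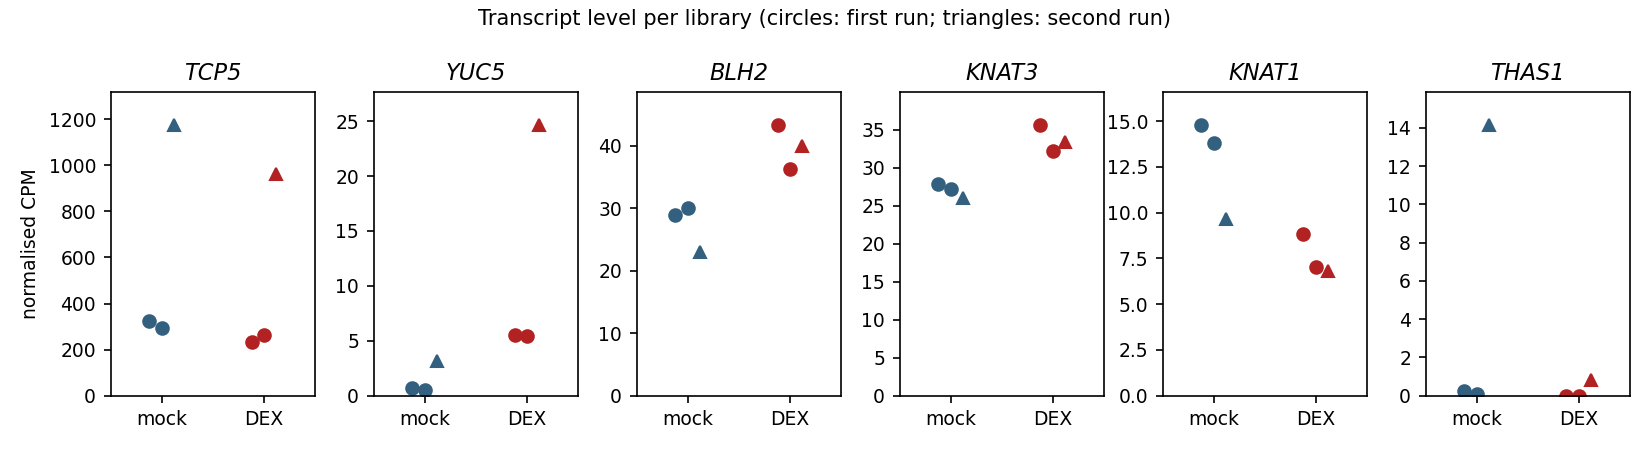
Normalised CPM of 6 genes in each library (n = 3 per group), mock in blue and DEX in red, with circles for the first run and triangles for the second. YUC5, BLH2 and KNAT3 lay higher in each DEX library than in each mock library, and KNAT1 lay lower. TCP5, YUC5 and THAS1 differed between runs, with TCP5 3.85-fold higher in the second.

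The fourth comparison asked whether groups of genes fixed before the data were examined moved together. Camera with a preset correlation of 0.01 called 8 of 31 lists. With an estimated correlation it called 0 (lowest adjusted p = 0.434), and the flavonoid list alone had an unadjusted camera p under 0.05 (0.0291). That form has little power with 6 libraries, since it tests on the residual degrees of freedom. For the brassinosteroid and abscisic acid lists the estimated correlations were negative (−0.13 and −0.05). Their unadjusted camera p still rose, from 0.0106 to 0.0773 and from 0.0107 to 0.0721. The 0 calls thus do not show whether correlation between members made the preset calls. Fry, which asks whether a list moves one way without comparing it with other genes, called 4. Those were the auxin synthesis list upward (fry adjusted p = 0.0292) and the brassinosteroid (0.0292), flavonoid (0.0383) and abscisic acid (0.0383) lists downward.

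Genes of auxin response and synthesis moved in both directions, though the falls of IAA17 and TAA1 lost their call with the replicate block. Of 19 auxin early response genes, 2 rose and 1 fell, and adjusted over the list alone 4 rose and 1 fell. The Aux/IAA repressor gene IAA1 rose by 1.05 ± 0.11 and GH3.5, which conjugates auxin to amino acids, by 0.47 ± 0.09, whereas IAA17 had a log2 fold change of −0.61 ± 0.13. The list was called upward (median log2 fold change 0.11, camera adjusted p = 0.0232; adjusted p = 0.434 with an estimated correlation). Of 8 auxin synthesis genes, YUC5 rose and TAA1, the aminotransferase that acts before the YUC enzymes, fell (log2 fold change −0.85 ± 0.17). Camera did not call that list (adjusted p = 0.0560), whereas fry called it upward (adjusted p = 0.0292).

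The CIN-class TCP genes, TCP5's own subfamily, included 3 that fell and 5 that did not pass over all genes. TCP10 had a log2 fold change of −0.69 ± 0.10, TCP13 of −0.50 ± 0.08 and TCP4 of −0.42 ± 0.09. TCP4 lost its call with the replicate block. Adjusted over the list alone, 5 of 8 fell, 1 of them TCP5 itself (adjusted p over the list 0.0280). The list and its camera test thus include the transcript of the transgene. The list was called downward (median −0.35, camera adjusted p = 0.0164; adjusted p = 0.447 with an estimated correlation). The call was also lost in the first run alone (adjusted p = 0.111) and without DEX replicate 2 (0.0623), DEX replicate 3 (0.134) or mock replicate 3 (0.109).

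Flavonoid and anthocyanin genes had the lowest camera p of the lists. Of 15 tested, 5 fell and 0 rose, and 8 fell adjusted over the list alone, with a median log2 fold change of −0.87. Chalcone synthase CHS, the first enzyme of the pathway, fell from 73.9 ± 20.2 to 40.5 ± 11.5 CPM. It overlaps AT5G13940, and TT19 overlaps AT5G17230. LDOX had a log2 fold change of −1.46 ± 0.21, TT19 of −1.22 ± 0.21 and F3'H of −0.95 ± 0.20. The regulator PAP1, named after its value was seen, had −1.33 ± 0.30. The camera adjusted p was 1.19e-07, and it was 0.434 with an estimated correlation.

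Among 11 cytokinin genes, the type-A response regulators ARR4 (−1.21 ± 0.23) and ARR15 (−1.76 ± 0.38) fell and 9 genes did not pass. Adjusted over the list alone, 2 fell. The camera adjusted p was 0.0113, and the adjusted p was 0.434 with an estimated correlation. Of 8 brassinosteroid genes 3 fell and 1 rose, also adjusted over the list alone. The synthesis genes ROT3 (−0.86 ± 0.10) and BR6OX2 (−0.73 ± 0.09) and the transcription factor gene BES1 (−0.71 ± 0.10) fell, and BAS1, which inactivates the hormone, rose by 1.14 ± 0.25. The list was called downward (camera adjusted p = 0.0413; adjusted p = 0.434 with an estimated correlation). With 1 library left out its call held only without DEX replicate 1 (adjusted p = 0.0460), and the adjusted p was 0.0729 to 0.263 without any other library and 0.0680 with the replicate block. ROT3 overlaps AT4G36370 and BES1 overlaps AT1G19360.

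Of 16 expansin and xyloglucan endotransglucosylase genes, whose products loosen or remodel cell walls, 3 fell and 0 rose, and 4 fell adjusted over the list alone. XTH15 had a log2 fold change of −1.17 ± 0.23, EXPA10 of −0.91 ± 0.12 and XTH4 of −0.75 ± 0.12 (camera adjusted p = 0.00973; adjusted p = 0.434 with an estimated correlation). XTH15 overlaps AT4G14120. Without DEX replicate 2 the list was not called (adjusted p = 0.0623). Of 10 heat-shock genes 1 passed over all genes, HSP101 (−0.50 ± 0.11), and 7 fell adjusted over the list alone (camera adjusted p = 6.62e-05; adjusted p = 0.447 with an estimated correlation). HSP101 overlaps AT1G74300. None of 15 abscisic acid and cold or drought genes passed over all genes, and 4 fell adjusted over the list alone (camera adjusted p = 0.0413; adjusted p = 0.434 with an estimated correlation). That list lost its call with the replicate block (adjusted p = 0.0680) and without DEX replicate 1 (0.100), DEX replicate 3 (0.0650), mock replicate 2 (0.0668) or mock replicate 3 (0.0650).

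**Figure D3:**
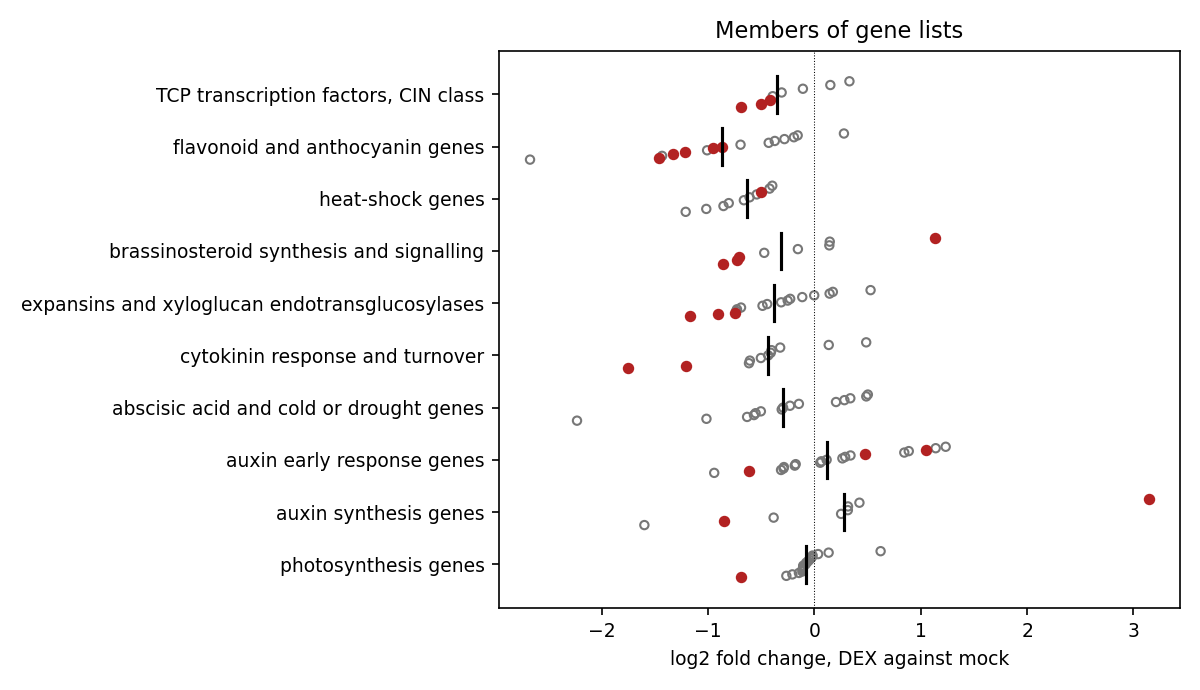
Log2 fold change, DEX against mock, of the tested members of 10 gene lists, with filled red points for genes with an adjusted p under 0.05, open points for the others and a black bar at each list's median. The flavonoid list had a median of −0.87, and YUC5 lay at 3.14 in the auxin synthesis list.

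The remaining lists were not called, and their members included single genes of leaf shape and growth. Of 18 leaf margin and boundary regulators, CUC3 (−2.48 ± 0.53) and the leaf polarity gene AS2 (−1.01 ± 0.22) fell and 16 did not pass; adjusted over the list alone 1 rose and 6 fell (camera adjusted p = 0.172). CUC3 was low, at 0.65 ± 0.53 CPM with mock and 0.12 ± 0.10 CPM with DEX, and lost its call with the replicate block. Of 16 reported outputs of CIN-class TCPs, YUC5 and BLH2 rose and CUC3 fell; adjusted over the list alone 4 rose and 3 fell. Of these 4, BLH2 and KNAT3 were listed from knowledge of the study and are not independent evidence. The camera test pointed up although the median log2 fold change was −0.23 (camera adjusted p = 0.211). Other rises were those of SPL3 (1.27 ± 0.17), a promoter of phase change that overlaps AT2G33815, and of the DELLA gene GAI (0.56 ± 0.10). The ethylene synthesis genes ACS8 (1.15 ± 0.22) and ACS11 (−1.14 ± 0.25) went opposite ways. The growth regulator gene GRF7 had a log2 fold change of −1.096 ± 0.23, the cell cycle inhibitor gene SMR1 of −0.69 ± 0.11 and the cyclin gene CYCD3;2 of −0.46 ± 0.09. CYCA2;3 rose by 0.77 ± 0.13. It overlaps AT1G15580, as SMR1 does AT3G10527, CYCD3;2 AT5G67265, RVE1 AT5G17305 and GRF7 AT5G08015. RVE1 of the clock list rose by 0.79 ± 0.16 and PRR9 fell by 0.73, and GLK2 of the photosynthesis list fell by 0.69. None of 23 jasmonate genes passed (camera adjusted p = 0.142). That list was called downward in the first run alone (adjusted p = 0.0159) and without DEX replicate 3 (0.0139), mock replicate 1 (0.0160) or mock replicate 3 (0.0121).

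Cell type markers were measured in the same way. None of 6 tested root markers passed (median log2 fold change −0.78, camera adjusted p = 0.155). That list was called downward without the run term (adjusted p = 0.0391) and, with 13 markers tested, without DEX replicate 1 (0.0364), mock replicate 1 (0.0185) or mock replicate 2 (0.0148). Of 7 tested abundant root transcripts, listed after the calls had been seen, 3 fell. None of 9 stomatal, 7 epidermal and 8 vascular markers did. Of 3 tested shoot meristem markers KNAT1 fell. Root transcripts differed mainly between runs. Of 25 listed root genes, 16 were at 1 CPM or more in both second-run libraries and at 0.851 CPM or less in each first-run library. In the second run, 15 of these 16 were lower in the DEX library than in the mock library, with a median log2 ratio of −1.08 from 1 library per group. NRT2.1, named after its value was seen, was the exception, at 1.32. These root levels and ratios are on raw library totals, without TMM.

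**Figure D4:**
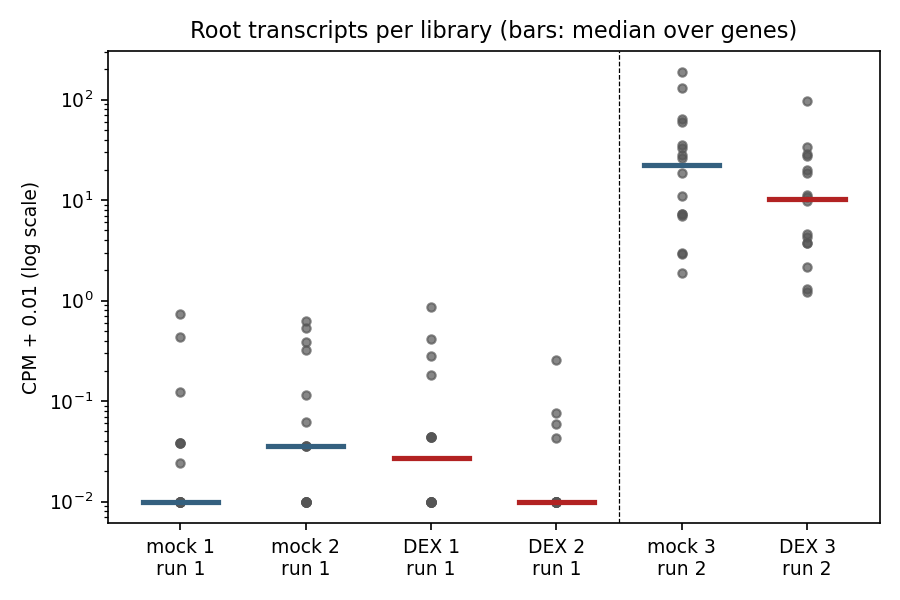
CPM plus 0.01, on a log scale, of the 16 root genes at 1 CPM or more only in the second run, in each library (points are genes, bars medians over genes). First-run libraries lie at or under 0.851 CPM, and in the second run the DEX library lies below the mock library for 15 genes.

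The last comparison asked whether the DEX effect differed between the 2 sequencing runs. The interaction of treatment and run passed for 0 genes with edgeR (1436 at an unadjusted p under 0.05) and for 0 with limma-voom (1160), with 1 library per group in the second run. Each of the 786 falls and 238 rises had the same direction in both runs, which the fit over both runs favours. The first run alone called 697 genes, and of the 696 that were also tested over both runs 92.5% had the same sign in the second. In the first run alone, 392 of the falls and 116 of the rises passed the test. The run itself changed far more genes, since the run term passed for 12174. The first principal component held 76.1% of the variance and separated the runs, and the second held 9.91% and separated DEX from mock.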

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

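Intron counts, which the comparisons above did not use, held a DEX signal of their own; the test of them was chosen after the files' columns were seen. Of 12989 genes with enough intron counts, 122 changed in introns (edgeR quasi-likelihood test, adjusted p under 0.05), 42 rising and 80 falling. Among them AT3G51660 had an intron log2 fold change of 1.57, UMAMIT44 of 1.53, UMAMIT45 of 1.41, ChiC of 1.61 and ELI3-1 of 1.04, and AT3G11930 had −1.41, AT1G27030 −2.20 and GLK2 −0.84. Of these 122 genes 72 had also changed in exons, each in the same direction. Of the 579 exon calls with testable introns 538 (92.9%) went the same way in introns, against 66.7% of 12794 genes testable in both. Exon and intron fold changes came from the same 6 libraries and so share their chance deviations.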

How the results depend on the processing

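No count, named gene or TCP5 value reversed its direction under an alternative, and the 8 called lists kept theirs in all 9 alternatives that refitted camera. Nearly all named genes, and the called lists, were picked for passing in these same libraries, which the alternatives reused. Reversals were thus unlikely from the start. Lists that were not called became called, the root marker and jasmonate lists in 4 of the 9, the mitotic list in 3 and the leaf margin and photosynthesis lists in 1. Such lists also changed direction, the BEL-like list in 4 of the 9, the KNOX list in 2, the photosynthesis and vasculature lists in 4, the clock list in 3, the ethylene and touch lists in 2 and the auxin synthesis, gibberellin and salicylic acid lists in 1. The counts moved far more than the directions did. Genes changed numbered 0 without the run term, 571 (109 rising, 462 falling) with the replicate block, 2065 with DESeq2 (all 1024 shared), 212 at an adjusted p under 0.01, 401 with glmTreat against 1.2-fold and 678 without overlapping loci, where fewer genes were tested. Leaving out 1 library gave 279 to 1132. Genes changed at least 2-fold numbered 0 without the run term, 513 with DESeq2, 123 at the stricter p and 217 without overlapping loci, and 173 to 361 with 1 library left out (173 without DEX replicate 2, 175 without mock replicate 2). KNOX and BEL-like genes called numbered 0 without the run term, 1 with the replicate block, 5 with DESeq2, 0 at the stricter p and 0 with glmTreat, and 0 to 2 with 1 library left out. It was 0 without mock replicate 1 or 2, and 1 without DEX replicate 2, DEX replicate 3 or mock replicate 3. Lists called numbered 0 with an estimated correlation, 4 with fry (3 shared), and 5 to 9 with 1 library left out (5 without DEX replicate 2). TCP5 passed with DESeq2 (log2 fold change −0.30, adjusted p = 0.0189; over the other tested alternatives 0.111 to 0.999). Except where the construction shows it, the cause was not tested.

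Beyond these, falling genes were 69.4% of the calls under total counts and 76.8% in the main result. With the replicate block 22 named genes lost their call, BLH2, TCP4, IAA17, TAA1, ARR4 and CUC3 among them, as did 22 in the first run alone, CYP705A5 and CYP708A2 among them. Without the run term 67 did. Without mock replicate 1, 2 or 3 it was 25, 33 and 29 named genes, and without DEX replicate 1, 2 or 3 it was 11, 31 and 25. With the block 6 lists were called, all shared. The abscisic acid and brassinosteroid lists lost their call (adjusted p = 0.0680 for both). Over the 9 alternatives the flavonoid, heat-shock, cytokinin and auxin response lists kept their call in 9, the expansin list in 7, the CIN-class TCP list in 5, the abscisic acid list in 3 and the brassinosteroid list in 1. Exon plus intron counts, halved counts, loci without overlaps, loci without ribosomal RNA and genes at 1 CPM or more in the first run were chosen after seeing the data. The stranded columns and the pseudocount were not run, because the files used hold neither strands nor normalised values. At this depth, simulated 1.5-fold changes were recovered in 32.8% of cases.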

Other observations

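The tests of root genes in single runs, of glucosinolate and thalianol genes, of the number of genes called by the run term and of the DEX effect in genes chosen from 1 pair were chosen after the results were seen. The genes named for them, such as PYK10, PBP1 and BGLU21, were chosen then too. Genes of aliphatic glucosinolate synthesis and transport were grouped after GTR2 was seen to fall. Of 20 such genes 4 fell over all genes: GTR2, SOT17 (log2 fold change −0.94 ± 0.15) and the regulators MYB28 (−0.61 ± 0.14) and MYB29 (−1.70 ± 0.14). The first run alone called 12 of them falling. Their median log2 fold change was −0.49, with −0.68 in the first run and −0.09 in the second. As a group they may have fallen, but the tests differ: fry gave p = 0.0425, whereas camera with an estimated correlation gave p = 0.138. The 3 tested thalianol genes all fell (camera p = 0.0137 with an estimated correlation), and were chosen because they fell.

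The binding core of CIN-class TCPs, GGACCA, was sought within 500 bases upstream of protein-coding genes, with the prediction written before the search. It lay upstream of 54 of 231 rising genes (23.4%) and 2290 of 19355 unchanged genes (11.8%), an odds ratio of 2.27 (95% interval 1.64 to 3.11; two-sided Fisher's exact p = 1.08e-06, adjusted p = 4.30e-06 over 4 tests). The odds ratio was 2.29 after adjustment for GC content and expression level. Falling genes carried it in 10.3% of cases (odds ratio 0.86, adjusted p = 0.418), and the shuffled GACAGC gave odds ratios of 0.70 for rising and 1.03 for falling genes. Some rising genes may therefore be direct targets of GR-TCP5. These data alone cannot settle that hypothesis, since no binding was measured and no plants without the construct received DEX. Changes seen after 4 h may also be secondary.

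More genes fell than rose after DEX. The choice among the scalings tried did not account for it, since falling genes were still 69.4% of calls under the scaling that lowered them most. Those scalings kept the median log2 fold change of all genes between 0.00 and 0.05. A larger scaling error was thus not tested as a source of the excess of falls. Less root tissue in the DEX libraries could account for part of it: the test written before these transcripts, but after the calls, had been looked at, the median log2 fold change of 7 tested abundant root transcripts, came to −1.11 (bootstrap SE 0.43), as that explanation predicts, and in the second run the 16 root genes had a median log2 ratio of −1.08. Genes under 1 CPM in each first-run library made up 47 of the 786 falls (5.98%) and 2 of the 238 rises (0.84%). Of all tested genes 10.8% were such. Without them, a setting chosen after seeing the data, 806 of 1044 calls fell (77.2%, against 76.8% with them). The excess of falls thus does not rest on such genes, but root transcripts present in both runs are not covered by this. Levels already seen argue against root tissue as the whole cause in the first run. Most listed root transcripts were nearly absent there, yet 76.4% of the calls fell. Over all 25 listed root genes the median ratio of the first-run to the second-run mock level was 0.00553 (bootstrap SE 0.0379). Since 16 of the 25 were known to be under 1 CPM in the first run, this median was bound to be low and restates that observation. It is also the 3rd form of root test tried, with a bound of 0.05 set afterwards and met only narrowly, so it carries less weight than the test written beforehand. BGLU21, XTH14 and PRP1 were at 0 CPM in each first-run library, and 7 of the 12 abundant root transcripts were under 1 CPM in every first-run library. Against that, the 7 tested transcripts had a first-run median log2 fold change of −0.86, but they did not move together there. TIP2;3 (0.71), PHT1;1 (2.04) and PHT1;4 (0.26) were higher with DEX in the first run. PHT1;1, and RCI3, which was lower with DEX, were under 1 CPM in that run. TIP2;3, PHT1;1 and PHT1;4 had log2 fold changes of −0.21, −0.28 and 0.13 over both runs, and of −1.67, −1.09 and −0.14 in the second. Of those 7 transcripts PYK10 (−1.11 ± 0.17) and PBP1 (−1.13 ± 0.18) also had first-run log2 fold changes of −0.93 and −0.97, at 252 to 711 CPM on raw library totals there, so they were present where most root transcripts were not. A biological effect of TCP5 stays open, and for genes seen mainly in the second run, THAS1 among them, root content and DEX cannot be separated here.

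The libraries split by sequencing run, and TCP5 was 3.85-fold higher in the second. The log2 difference in TCP5 was 1.83 after all libraries were thinned to one total and 1.95 before. CPM are already scaled to depth, and TCP5 was at 233 CPM or more in each library. Thinning could thus hardly move the difference, and its result is no evidence about depth. Root tissue in the second-run libraries is a candidate explanation for the split, because 16 of 25 listed root genes were at 1 CPM or more there and under 1 CPM in the first run. The labels call all 6 samples seedlings. A first-run harvest without roots would be the same explanation. How much of the split came from other differences in sequencing, growth or harvest cannot be told. The run term called 12174 genes, and the labels give only the run.

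Whether the DEX effect was larger in the second run, where TCP5 was higher, was also tested. An initial comparison on genes called in the first run gave medians of 0.95 there and 0.58 in the second run, but selecting in the first run inflates the former. It was replaced by a comparison on 500 genes chosen in 1 first-run pair and measured in the other pairs. The median difference, second-run pair minus the first-run pair not used, was −0.0636 ± 0.0639 for genes chosen in pair 1 and 0.0637 ± 0.0702 for those chosen in pair 2 (bootstrap SE). The median change itself was lower in the second-run pair for both choices (0.583 against 0.409 for pair 1, 0.852 against 0.775 for pair 2), whereas the median differences had opposite signs and each lay within its SE, so a larger effect in either run stays open.

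Other splits of the 6 libraries into 3 and 3 were fitted with the run term; 3 against 3 give only 10 splits, so no share can fall under 0.1. The real split gave 1024 genes changed, 327 changed at least 2-fold and 2 KNOX and BEL-like genes, and the highest of the others gave 0 in each case, so that 1 split, the real one, reached each value. The other splits leave differences between DEX and mock in the residual spread. Their 0 calls are therefore no evidence that the 1024 are sound. For the lists, 4 of the 10 splits, the real one included, gave 8. Of the other 3 splits that also part all 3 pairs, 1 gave 3 lists and 2 gave 8, with 0 genes changed. List calls at the preset correlation thus also appear in splits that mix the treatments, though these splits still hold part of the DEX contrast.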
